A study of Mus musculus with 6 samples.

How the data were processed

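DNA methylation was profiled in ventricular heart tissue of male C57BL/6 mice at postnatal days 1 (P1) and 14 (P14), with 3 libraries per age that the labels call biological replicates. Per the labels' protocols, sonicated genomic DNA was enriched with a kit that captures methylated CpG sites through a methyl-CpG binding domain (MBD-seq), and the captured fragments were sequenced on a Genome Analyzer IIx. Capture of this kind gives read density, which depends on how many methylated CpGs a fragment holds as well as on the capture of each library, and gives no methylation level per site.

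The deposited table holds whole-number read counts per region, not divided by depth or length. The submitters' processing notes name BWA, MACS, bedtools and edgeR 3.2.4 and the build GRCm38 (mm10), without saying which step each tool made. Peak-calling settings, the handling of duplicate reads and whether libraries were pooled for peak calling are not given in the sources used here. The table has 221524 lines, of which 7567 repeat a region for a further gene with identical counts, leaving 213957 distinct regions. No region had a mean below 10 reads per library, so low regions had been removed before deposit. The regions tile the chromosomes as short peaks that alternate with long stretches between them. This reading was inferred here from the region borders, the gene names and the read density, since the table has no column for it. The inference gave 101267 peaks with a median width of 852 bp, 112654 stretches between peaks with a median width of 11049 bp, and 36 unplaced scaffolds or mitochondrial regions. For 17543 regions the density of reads was the only evidence, and among the regions settled by their borders or names the density rule gave the same answer for 94.3%. Gene symbols and Ensembl identifiers are those of the table, which names genes for 68634 of the peaks. A peak at a gene is one that the table assigns to it, and it need not lie in the RefSeq span of that gene. The place of a region relative to genes was taken from RefSeq gene spans of the assembly GRCm38.p6, which has the same coordinates: inside a gene span, within 5 kb of one, or intergenic. A peak inside a gene span could not be assigned to a promoter, exon, intron or UTR, because no transcript structure, strand or genome sequence was used here. For the same reason no value was corrected for CpG density.

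All 6 value columns carry the name of 1 library each. Total reads over distinct regions ranged from 16284216 to 21512072 per library. The median peak held 14 to 48 reads per library. In simulated counts drawn from the means and dispersions of these libraries, the test over all 209063 regions recovered 4 of 100 regions changed 2-fold and 56 of 100 changed 4-fold, with 2 false calls among 62. Over the 96785 peaks it recovered 4 of 100 changed 2-fold and 53 of 100 changed 4-fold, with 4 false calls among 61. The simulated regions varied independently, without differences between libraries in the share of reads in peaks. Unadjusted p under 0.05 made up 4.84% of unchanged regions and 4.6% of unchanged peaks there, against 23% of regions and 7.6% of peaks in the data. The false calls are therefore no estimate for the real libraries.

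Differences between ages were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the deposited counts of all 6 libraries, with TMM factors, the default expression filter, age as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 209063 regions and removed 4894. This fit over all regions, its alternatives, 23 gene lists and the rule for named regions were fixed before the data were examined. A further fit of the same form over the 96785 peaks alone was chosen after seeing the data, because the libraries differed in the share of reads in peaks and a scaling over all regions carries that difference into every peak. Values per peak are TMM-scaled CPM over the reads in peaks, as mean ± SD over 3 libraries, and the standard error of a log2 change is its size divided by the square root of the F statistic. Peaks are called gained or lost where they passed the threshold with a higher or lower value at P14. These words describe captured reads relative to the other regions in the fit.

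Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 23 lists. Of 788 distinct list genes, 566 are named in the table, 4 of them under a synonym. The genomic place of gained and lost peaks was compared with all other tested peaks by Fisher's exact test, two-sided, adjusted over 6 tests. Neighbouring peaks are not independent replicates, so these p-values are lower than independent regions would give. Shares of reads per library were compared by exact permutation tests, two-sided, for which 3 libraries against 3 give a smallest p of 0.1.

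Named peaks followed 1 rule. It took the 10 gained and 10 lost peaks with the largest change among those past the threshold, with a gene name, abundance above the median and no overlap between the ages, at 1 peak per gene. It also took up to 4 genes per list by the smallest p among peaks past the threshold, or 2 given as values where none passed, and the 3 regions with the smallest p in each direction. Written for the fit over all regions, the rule was applied there first and then in the same form within the peaks. Alternatives were DESeq2 1.42.0, edgeR's exact and likelihood ratio tests, limma-voom, other scalings and filters, the replicate number as a block, a stricter threshold, autosomes alone, and each library left out. Called peaks were chosen with all 6 libraries, so their median change in an alternative fit is not independent evidence of a difference. Chosen after seeing the data were the likelihood ratio test, the enrichment of each library as a covariate, removal of both replicates 1, and scaling to the reads between peaks. The enrichment, the log2 ratio of reads in peaks to reads between them, was higher in every P14 library than in every P1 library. It is thus confounded with age, and a change that shrinks with this covariate can reflect either. The deviations of same-numbered libraries from their group means correlated across peaks at -0.049, -0.046 and 0.02, so no pairing by replicate number was seen. Libraries of unlike number gave -0.036 to 0.068. These correlations cannot exclude that libraries of the same number were prepared together. No pair of libraries of the same age agreed within counting noise, with chi-square per degree of freedom of 1.39 to 8.72, so no library was treated as a repeat deposit of another. This does not show that the libraries came from separate captures or animals.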

Results

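The data compare captured, methylated DNA of the mouse ventricle on the first day after birth and at 14 days, an interval in which heart muscle cells largely stop dividing and grow in size instead. There were 3 libraries at P1, with 18505983, 17532547 and 18101856 reads for replicates 1 to 3, and 3 at P14, with 21512072, 20027789 and 16284216 reads. Coordinates are those of GRCm38.

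Peaks, the regions in which methylated DNA had been enriched, took a larger share of reads at P14 in every library. They held 12.5% ± 0.907 (SD, n = 3) of reads at P1 and 22.2% ± 7.9 (SD, n = 3) at P14. The difference of 9.72 percentage points had an exact permutation p of 0.1, the smallest possible with 3 libraries against 3. P14 replicate 1 stood apart at 31.33%, beside 18.41% and 17.0% in the other P14 libraries, and without it the P14 mean was 17.7%. The stretches between peaks held 86.0% to 87.8% of reads at P1 and 68.51% to 82.35% at P14. Read density in peaks relative to these stretches was 3.23 ± 0.265 (SD, n = 3) at P1 and 6.65 ± 3.12 (SD, n = 3) at P14. The X chromosome took 2.0% ± 0.0876 of reads at P1 and 1.48% ± 0.388 at P14 (SD, n = 3, exact permutation p = 0.1), and without P14 replicate 1 the P14 mean was 1.7% and the difference -0.306 in place of -0.528 percentage points. Within the reads in peaks the share on X was 0.328% at P1 and 0.303% at P14, a difference of -0.0246 percentage points. Reads on Y made up 0.0383% ± 0.0022 at P1 and 0.0332% ± 0.00613 at P14 (SD, n = 3, exact permutation p = 0.3), with reads on Y in all 6 libraries, all labelled male.

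**Figure D1:**
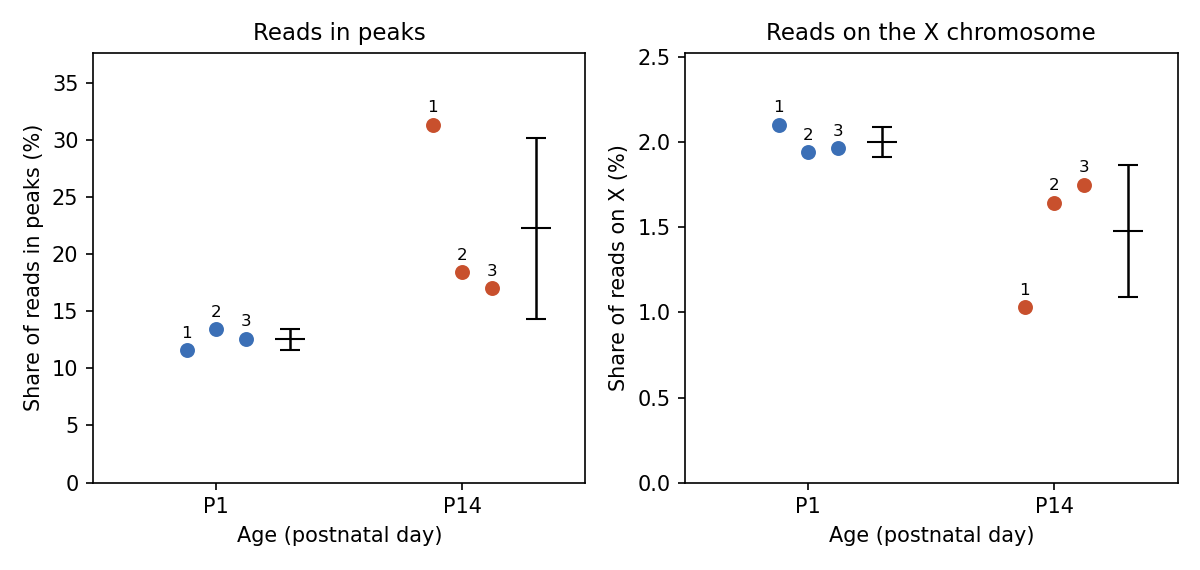
Share of reads in peaks (left, %) and on the X chromosome (right, %) in each library, with the replicate number above each point and the group mean ± SD beside it (n = 3 per age). All P14 libraries lie above the P1 libraries in the share in peaks, with P14 replicate 1 at 31.33%, and below them in the share on X.

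Across all regions, the 3 with the smallest p for a higher value at P14 were peaks at Egr3, AI848285 and Mdk. Egr3 encodes a zinc finger transcription factor induced by growth signals, and Mdk the growth factor midkine. The Egr3 peak (ENSMUSG00000033730, chromosome 14, 70078916 to 70080874, inside the gene span) held 5, 12 and 7 reads at P1 and 186, 78 and 44 at P14, a log2 change of 3.23 (SE 0.47). The Mdk peak (chromosome 2, 91930738 to 91931990) held 5, 3 and 6 reads against 81, 32 and 29, a log2 change of 2.91 (SE 0.47). The AI848285 peak on chromosome 15 had a log2 change of 3.61 (SE 0.56). In the other direction the smallest p values were at Neat1, the long noncoding RNA that scaffolds nuclear paraspeckles, at Dimt1, an rRNA methyltransferase, and at an intergenic peak on chromosome 4 (70032039 to 70032818). The Neat1 peak (ENSMUSG00000092274, chromosome 19, 5843467 to 5844277, inside the gene span) held 30, 21 and 37 reads at P1 and 9, 7 and 5 at P14, a log2 change of -2.39 (SE 0.42). The Dimt1 peak had a log2 change of -3.02 (SE 0.53) and the intergenic one of -2.80 (SE 0.48). None of these 6 passed the test, each with an adjusted p of 0.214 in edgeR's quasi-likelihood fit.

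Of 209063 regions tested in this fit, 0 had an adjusted p under 0.05, while 48109 had an unadjusted p under 0.05. DESeq2 called 83 regions, 82 of them higher at P14, edgeR's exact test 1057 and limma-voom 0. The likelihood ratio test, added after seeing the data, called 2151. The median log2 change was 0.73 over peaks and -0.29 over the stretches between them, so most peaks moved together against the rest of the genome. Without P14 replicate 1 the same test called 3341 regions, 353 higher and 2988 lower at P14, of which 351 and 26 were peaks. Without both replicates 1 it called 7696, 2562 higher and 5134 lower, of which 2542 and 179 were peaks. The lower regions in these fits thus lay nearly all outside peaks. With any other single library left out the test called 0.

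All 23 gene lists had higher values at P14 than other regions when all regions were the background, with camera adjusted p from 1.28e-15 for Wnt signalling to 0.0151 for Hox genes. With an estimated correlation none passed, with adjusted p from 0.266 to 0.275. The table names genes only at peaks, so each list was compared with a background made largely of stretches between peaks. No list gene had a peak past the threshold in that fit, where the smallest p over the lists was 0.000117 (adjusted p = 0.214), at Tbx2.

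In a fit within the peaks alone, chosen after seeing the data, the Egr3 peak rose from 3.7 ± 1.5 to 20.6 ± 5.0 CPM (SD, n = 3), which was 5.52-fold (log2 change 2.46, SE 0.34, adjusted p = 0.0242). A peak that the table assigns to Gata2, the gene of a blood and endothelial transcription factor (ENSMUSG00000015053), lies in the RefSeq span of Gm38708 (chromosome 6, 88190014 to 88191408) and rose from 2.4 ± 1.6 to 12.7 ± 4.1 CPM (SD, n = 3). A peak at Hlx, a homeobox gene (chromosome 1, 184727159 to 184728438), rose 4.46-fold, and one at Lhx6, a LIM homeobox gene (chromosome 2, 36090263 to 36091972), rose 3.47-fold. The tendon transcription factor gene Scx shares a gained peak on chromosome 15 (76457202 to 76458410) with Bop1, and the table assigns it to both genes. Gained peaks also lay at Shank3, which encodes a synaptic scaffold, at Scarf2, a scavenger receptor gene, at 2700081O15Rik, at Dnase2a with Mast1, and at Gm13146 with a pair of clone-named genes. Among gained peaks with a gene name, abundance above the median and no overlap between ages, these 10 had the largest changes, from 3.3-fold to 6.21-fold, with adjusted p between 0.0242 and 0.0402. With P14 replicate 1 left out no peak passed within peaks, these 10 included. Their log2 changes fell from 2.63 to 1.63 at Gm13146 and from 2.47 to 1.52 at Scx. At Egr3 the change fell only from 2.46 to 2.27, and at Gata2 from 2.42 to 2.3. Plekhg5 had one of the 3 smallest p values among peaks higher at P14 and rose 3.2-fold (chromosome 4, 152107319 to 152108849).

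With peaks scaled to each other, those lost by P14 were more numerous. The Neat1 peak fell from 14.0 ± 4.0 to 1.6 ± 0.3 CPM (SD, n = 3), which was 8.78-fold (log2 change -3.13, SE 0.42, adjusted p = 0.0242). A peak at Tpst2, a tyrosine sulfation enzyme gene (chromosome 5, 112289770 to 112291301), fell from 25.2 ± 9.5 to 5.7 ± 1.3 CPM (SD, n = 3). An intergenic peak on chromosome 11 (112089708 to 112091054) fell from 18.8 ± 2.9 to 4.8 ± 0.6 CPM (SD, n = 3). Chosen in the same way, the 10 lost peaks with the largest changes fell 5.31-fold to 6.14-fold. They lay at Orc5, a subunit of the origin recognition complex, at Arhgap29, Gm765, Pdcl and Pan3, at Derl2 with Mis12, at Gpatch2 and Fnbp1l, at Vti1a with Zdhhc6, and at Upf2, a factor of nonsense-mediated mRNA decay. In all 10, P1 replicate 1 held the most reads of the P1 libraries. By CPM it was the highest P1 library in 82.3% of all 2377 lost peaks, against 37% of peaks not called. Of the 2377, 311 stayed lost without it. With that library left out 4 of the 10 passed, and their log2 changes, -2.62 to -2.41 with it, were -2.13 to -1.4, the smallest at Gm765 (-2.45 with it). The Arhgap29 peak (chromosome 3, 121987959 to 121989273) held 63 reads in that library, beside 35 and 30 in the other P1 libraries and 9, 20 and 16 at P14.

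**Figure D2:**
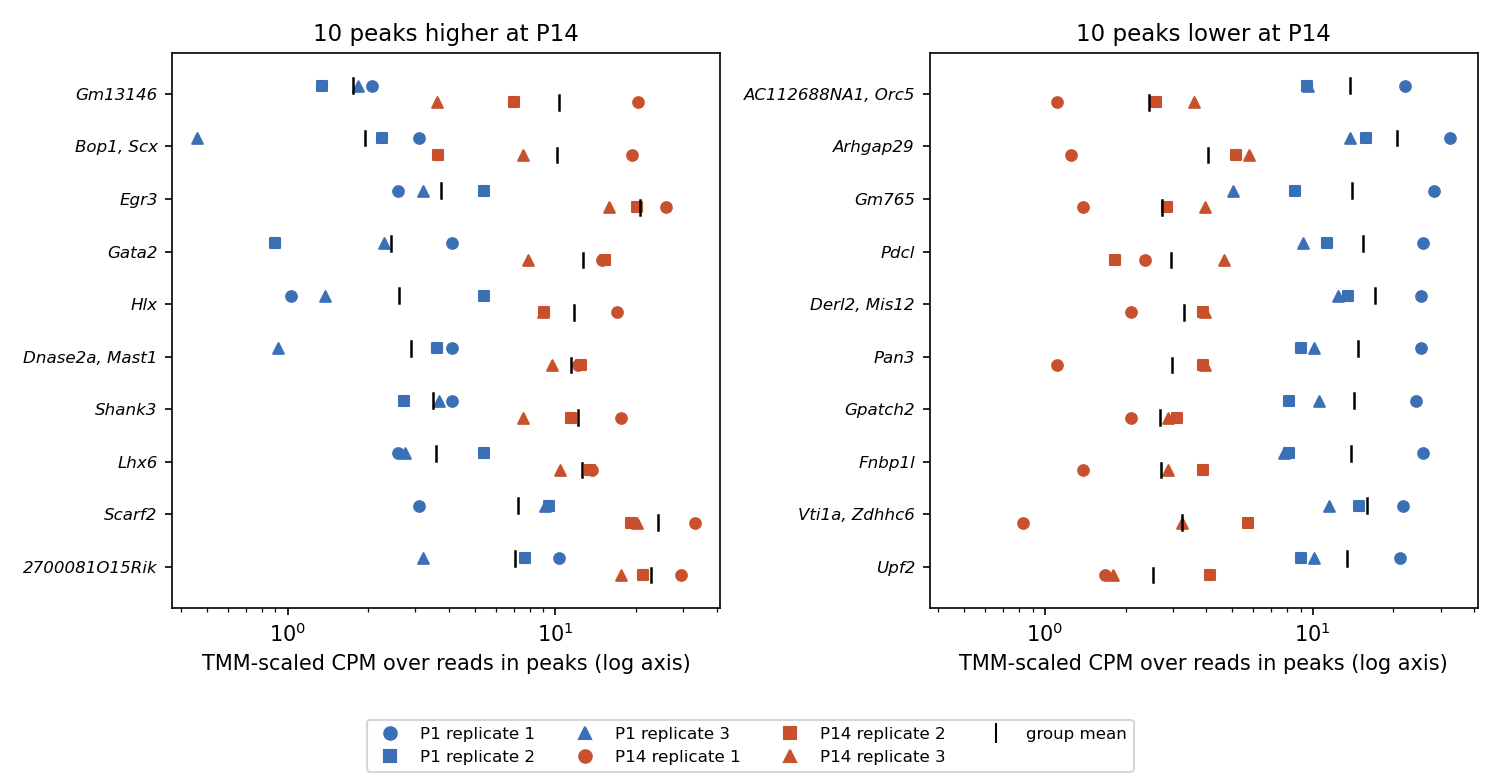
TMM-scaled CPM over the reads in peaks (log axis) in each library for the 10 gained and 10 lost peaks with the largest changes among those with a gene name, abundance above the median and no overlap between ages. Symbols mark replicates and black bars group means, the Egr3 peak lying at 3.7 on average at P1 and 20.6 at P14. Peaks named for several genes carry up to 2 of the names.

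Of 96785 peaks tested, 102 were gained and 2377 lost at an adjusted p under 0.05 in edgeR's quasi-likelihood test, and 0 passed 0.01. The gained peaks had a median log2 change of 1.47 and a median width of 1430.5 bp, the lost ones -2.12 and 732 bp, and peaks not called a width of 874 bp. Lost peaks held few reads, with a median of 20.3 per library at P1 and 9.3 at P14. The medians were 13.8 and 91.8 in gained peaks and 15.3 and 32.7 in peaks not called. Relative to the mean peak of each library, read density above that between peaks had a median of 1.49 at P1 and 0.22 at P14 in lost peaks, and of 0.19 and 1.28 in gained peaks. Groups did not overlap in 11.9% of all tested peaks, where chance gives 10%. The split between gained and lost depended on the scaling. Scaled to the reads between peaks, which shifted the median log2 change of all peaks to 1.18, 7275 were gained and 51 lost. An upward shift of this kind cannot turn a gained peak, and all 102 passed. All 2377 lost peaks were still lower at P14, of which 51 passed, Neat1 among them. With no TMM factor the median was 0.15, and 74 were gained and 700 lost. Leaving out P14 replicate 1 left 0 calls. The median log2 change was then 1.25 in the peaks called gained with all libraries and -1.71 in those called lost. The remaining libraries had helped choose these peaks, so medians on the same side follow partly from the choice. Of these peaks, 82 gained and 25 lost ones passed in the same direction in the fit over all regions without P14 replicate 1. Without P1 replicates 1, 2 or 3 there were 373, 977 and 934 calls, without P14 replicates 2 or 3 there were 1382 and 1470, and without both replicates 1 there were 323. P1 replicate 1 had 2394 peaks without a read, beside 30 and 37 in the other P1 libraries.

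**Figure D3:**
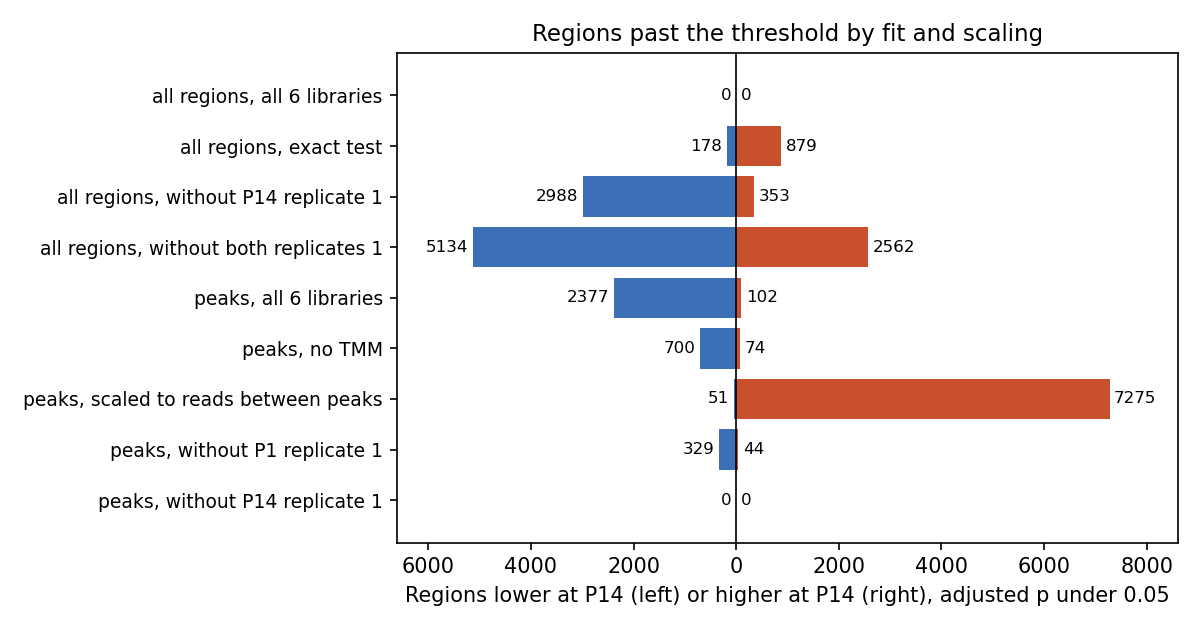
Number of regions past an adjusted p of 0.05 that were lower (left) or higher (right) at P14, by the regions fitted, the scaling and the libraries left out. Lost peaks outnumber gained ones, 2377 to 102, when peaks are scaled to each other, and gained ones outnumber lost ones, 7275 to 51, when peaks are scaled to the reads between them. Among all regions, those called lower without P14 replicate 1 (2988) or without both replicates 1 (5134) included only 26 and 179 peaks.

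Among genes of heart muscle function, all peaks that passed were lost, as were 2377 of the 2479 that passed among all peaks, and none of them passed when scaled to the reads between peaks. That scaling raised all peaks and gave 34 gained peaks and 0 lost in the calcium list, 12 and 0 in the fatty acid list, 34 and 0 in the sarcomere list, 20 and 0 among cardiomyocyte markers, and 9 and 0 in the glycolysis list. Of 33 calcium handling and ion channel genes with a tested peak, 7 had lost peaks and 0 gained ones, with 18 of 347 peaks lost. They included Ryr2, the calcium release channel of the sarcoplasmic reticulum (log2 change -2.33, SE 0.46), and Atp2a2, its calcium pump, whose peak on chromosome 5 (122455642 to 122456400) fell 4.59-fold. A peak at Itpr1, 1 of 3 lost among its 32 tested, fell 4.4-fold, and a peak at Cacna2d1 fell 4.78-fold. Without P1 replicate 1 their log2 changes were -1.31 (-2.14 with it) and -1.71 (-2.26 with it). Of 30 genes of fatty acid oxidation and mitochondrial metabolism, 6 had lost peaks, with 7 of 194 peaks lost. Peaks at Hadha and Acadl, which encode enzymes of beta-oxidation, fell 4.11-fold and 5.57-fold. In the same list a peak at Acacb, whose product restrains fatty acid entry into mitochondria, fell 4.63-fold. A peak at Esrrg, a nuclear receptor gene, fell 3.92-fold, 1 of 2 lost among its 27 tested. Without P1 replicate 1 the log2 change was -1.25 at Esrrg (-1.97 with it) and -2.18 at Acacb (-2.21 with it). Of 31 sarcomere and contractile genes, 2 had lost peaks, Ttn (3.16-fold) and, by the table's assignment, Cmya5 (6.82-fold), whose peak lies in the RefSeq span of Tent2. The 19 cardiomyocyte marker genes had 10 of 94 peaks lost, all at Ryr2 and Ttn, which are also members of the lists above. Adjusted over the list alone, 21 calcium and channel peaks, 9 fatty acid peaks, 3 sarcomere peaks and 12 cardiomyocyte peaks were lost, and 2 cardiomyocyte peaks were gained. Called peaks made up 5.19% of the peaks in the calcium list, 3.61% in the fatty acid list and 1.32% in the sarcomere list. The share was 10.64% among cardiomyocyte markers, against 2.56% of all tested peaks. None of these lists differed from other peaks by camera, with adjusted p of 0.836, 0.61, 0.33 and 0.761. The sarcomere list had a positive median of 0.05, against the direction of its 3 lost peaks, and the calcium list a median of 0.0 with a mean of -0.07. Of the 24 glycolysis and glucose uptake genes, 0 had a called peak. The smallest p values there were at Tpi1, shared with Usp5 and in the span of Usp5 (log2 change -0.63, SE 0.25, adjusted p = 0.354), whose sign turned to 0.62 when scaled to the reads between peaks, and at Slc16a3 (0.60, SE 0.27, adjusted p = 0.536). The Slc16a3 change was 1.92 and passed under that scaling (adjusted p = 0.04), and turned to -0.06 with the enrichment of each library as a covariate. No peak of these lists passed within peaks without P14 replicate 1. The peaks called lost with it then had a median log2 change of -1.78 in the calcium list (-2.17 with it) and -1.84 in the fatty acid list (-2.15 with it).

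Developmental regulators held both gained and lost peaks. Non-cardiac developmental transcription factors were the 1 list of 23 that was higher at P14 relative to other peaks (median log2 change 0.12, camera adjusted p = 0.0177), over 105 peaks of 26 genes. The call did not hold with an estimated correlation (adjusted p = 0.211), and it was lost without P1 replicate 2 (adjusted p = 0.197), P1 replicate 3 (0.0571), P14 replicate 1 (0.0593) or P14 replicate 3 (0.0632). Lhx6 was its 1 gene with a gained peak, also adjusted over the list alone, and it had 0 lost peaks. Of 25 cardiac transcription factor genes, 2 had gained peaks and 3 lost ones. Peaks at Tbx2 and Tbx3, T-box repressors of the conduction system and the outflow region, rose 2.75-fold and 3.0-fold, while peaks at Zfpm2, a cofactor of GATA factors, and Foxp1 fell 6.45-fold and 5.08-fold. The Tbx2 peak lay on chromosome 11 (85836381 to 85838783) and rose from 5.5 ± 1.5 to 15.4 ± 3.3 CPM (SD, n = 3). Called peaks made up 3.27% of the cardiac factor peaks and 0.95% of the non-cardiac ones, against 2.56% of all tested peaks. The counts adjusted over the list alone were 3 cardiac transcription factor peaks gained and 5 lost (camera adjusted p = 0.239). Only 2 of 39 Hox genes had a tested peak, neither of which passed over all peaks, though 1 was gained when adjusted over the list alone. The Hoxb3 peak, shared with Gm11536, had a log2 change of 1.43 (SE 0.49, adjusted p = 0.174), and the Hoxd3 peak, shared with 1700109F18Rik, of 0.50 (SE 0.51, adjusted p = 1). Asked whether the peaks of the developmental list moved in one direction, without regard to other peaks, fry gave an adjusted p of 0.0916. The Hox list had a camera adjusted p of 0.0806, and with P1 replicate 3 left out it passed at 0.0463. Without P14 replicate 1 none of these peaks passed within peaks. The cardiac factor peaks called gained with it then had a median log2 change of 1.41 (1.52 with it) and those called lost -2.04 (-2.34 with it). When scaled to the reads between peaks, 23 cardiac factor peaks were gained and 0 lost, 16 and 0 in the non-cardiac list, and 1 and 0 in the Hox list, the peak at Hoxb3 (adjusted p = 0.0178).

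Of 4 signalling lists taken from pathways that the study named on these samples, which are therefore not independent evidence of a direction, none differed from other peaks. Of 44 Wnt genes, 2 had gained peaks and 1 a lost one. Peaks at Axin2, a negative feedback regulator (shared with Gm11670), and Wnt7b rose 2.06-fold and 2.49-fold, and a peak at Dkk2, a Wnt antagonist, fell 4.04-fold, a change that turned to 0.03 with the enrichment of each library as a covariate, as did that of Gli3 below. With that covariate the log2 change of Wnt7b fell from 1.32 to 0.08 and that of Axin2 from 1.04 to 0.42. No Wnt peak passed when adjusted over the list alone (camera adjusted p = 0.268). Of 18 Hedgehog genes, 2 had lost peaks, the pathway repressor Sufu (3.9-fold) and the transcription factor Gli3 (5.31-fold), and 0 passed when adjusted over the list alone (camera adjusted p = 0.239). Of 40 BMP and TGF-beta genes, 6 had lost peaks and 1, Ltbp3, a gained one. Peaks at the receptor genes Bmpr1a and Acvr1 fell 5.16-fold and 4.98-fold. The Acvr1 peak lay in no gene span but within 5 kb of a gene. Peaks at Smad1, a signal transducer gene, and Ltbp1 fell 2.96-fold and 3.49-fold. In this list 1 peak was gained and 8 were lost when adjusted over the list alone (camera adjusted p = 0.422). Of 21 FGF genes, peaks at Spry2, a feedback inhibitor, and at Frs3, shared with Gm14873, rose 2.74-fold and 2.43-fold. Peaks at Fgf12 and at Fgfr2, shared with Ctbp2 and in the span of Ctbp2, fell 4.44-fold and 5.54-fold. Adjusted over the list alone, 2 FGF peaks were gained and 2 lost (camera adjusted p = 0.598, with a median of -0.01 and a mean of 0.03). Ltbp3 lies outside the rule for named genes and was named after its values were seen. Called peaks made up 1.12% of Wnt, 1.23% of Hedgehog, 3.7% of BMP and TGF-beta and 1.54% of FGF peaks, against 2.56% of all tested peaks. Within peaks none of the signalling peaks passed without P14 replicate 1. Median log2 changes were then -1.66 in the lost BMP and TGF-beta peaks (-2.13 with it) and 0.78 in the gained Wnt peaks (1.18 with it). Scaling to the reads between peaks gave 41 gained Wnt peaks, 25 Hedgehog, 32 BMP and TGF-beta and 22 FGF peaks, with 0 lost in each.

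Of 36 cell cycle genes, 1 had a gained peak, Cdkn1c, an imprinted gene that encodes a cyclin-dependent kinase inhibitor. That peak (chromosome 7, 143458487 to 143461261) rose from 9.3 ± 3.5 to 24.5 ± 6.8 CPM (SD, n = 3), which was 2.7-fold (adjusted p = 0.0254). Among 48 imprinted genes it was also the 1 gained, and 4 had lost peaks, among them Herc3 (6.52-fold), Ppp1r9a (3.04-fold) and Sfmbt2 (4.87-fold). Of 26 DNA methylation and chromatin enzyme genes, with 144 tested peaks of which 6 were lost, 5 had lost peaks and 0 gained ones. These were the demethylation genes Tet2 (4.05-fold), Tet3 (5.91-fold) and Tdg (4.19-fold), the cytidine deaminase gene Apobec1 (5.66-fold), and Hdac7, named after its values were seen. Of 30 Igf, insulin and thyroid hormone genes, Pik3r1 (6.61-fold), Irs1, shared with Gm9747 (6.46-fold), and Ncor1 (5.09-fold) had lost peaks. Of 21 Notch genes, 1 had a gained peak, Numbl, which shares it with Adck4 and Gm15567 by the table, in the RefSeq span of Coq8b (5.56-fold). That peak held only 2, 2 and 2 reads at P1, and 48, 23 and 9 at P14. Adjusted over the list alone, 1 cell cycle peak was gained, 1 imprinted peak was gained and 4 lost, 6 chromatin enzyme peaks and 4 insulin and thyroid peaks were lost, and 0 Notch peaks passed. The camera adjusted p values were 0.336, 0.377, 0.81, 0.635 and 0.33. Called peaks made up 4.17% of chromatin enzyme, 2.12% of imprinted and 1.63% of insulin and thyroid peaks, against 2.56% of all tested peaks. The share was 0.87% in the cell cycle list and 0.61% in the Notch list. Within peaks no peak of these lists passed without P14 replicate 1. The lost chromatin enzyme peaks then had a median log2 change of -1.98 (-2.07 with it) and the Cdkn1c peak of 1.19 (1.43 with it). Under the scaling to reads between peaks, 10 chromatin enzyme, 28 imprinted, 26 insulin and thyroid, 21 Notch and 5 cell cycle peaks were gained and 0 lost.

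Marker genes of other heart cell types did not differ as lists from other peaks. Of 20 endothelial markers, Esam, Erg and Fli1 had lost peaks (4.38-fold, 3.2-fold and 4.14-fold), with a median of 0.0, a mean of -0.02 and a camera direction that was positive (adjusted p = 0.785). Of 22 fibroblast and matrix markers, Has1, a hyaluronan synthase gene, had a gained peak (2.89-fold, camera adjusted p = 0.426). Of 23 macrophage and leukocyte markers, Mrc1 had a lost peak (5.09-fold, camera adjusted p = 0.598). Of 17 neural and Schwann cell markers, Elavl4, an RNA-binding protein gene of neurons, and Nefm had lost peaks (11.2-fold and 4.22-fold, camera adjusted p = 0.377). The Elavl4 peak held 25, 18 and 13 reads at P1 and only 3, 3 and 4 at P14, near the read density between peaks. The Nefm peak lay in no gene span but within 5 kb of a gene. Adjusted over the list alone, 3 endothelial, 1 macrophage and 2 neural peaks were lost and 0 fibroblast peaks passed. Of 8 erythroid and 15 smooth muscle and pericyte markers, 0 had a called peak, also adjusted over the list alone (camera adjusted p = 0.33 and 0.61). The smallest p values there were at Spnb1 (log2 change 1.06, SE 0.42, adjusted p = 0.374), Klf1 (0.71, SE 0.32, adjusted p = 0.541), Synpo2 (-1.70, SE 0.60, adjusted p = 0.203, turned to 0.18 with the enrichment covariate) and Myh11 (0.70, SE 0.33, adjusted p = 0.639). Called peaks made up 2.13% of endothelial, 0.62% of fibroblast, 0.89% of macrophage and 2.86% of neural peaks, against 2.56% of all tested peaks. Within peaks no marker peak passed without P14 replicate 1, and the lost endothelial peaks had a median log2 change of -1.41 (-2.05 with it). The scaling to reads between peaks gave 9 gained endothelial, 20 fibroblast, 4 macrophage, 9 neural, 7 erythroid and 2 smooth muscle peaks, Spnb1, Klf1 and Myh11 among them (adjusted p = 0.0212, 0.0353 and 0.0413), and 1 lost peak, a neural one.

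Gained peaks lay mostly inside genes, and lost peaks were more often intergenic. Of 102 gained peaks, 96 (94.1%) lay inside a gene span, against 73.7% of other tested peaks (odds ratio 5.72, Fisher's exact test, adjusted p = 3.88e-07), and 3 were intergenic. Of 2377 lost peaks, 1579 (66.4%) lay inside a gene span, against 73.9% of others (odds ratio 0.7, adjusted p = 5.85e-15), and 609 (25.6%) were intergenic, against 18.5% (odds ratio 1.52, adjusted p = 2.27e-16). The share within 5 kb of a gene did not differ (adjusted p = 0.108 for gained and 0.506 for lost). With P1 replicate 1 left out, the odds ratio of lost peaks for gene spans was 0.993 and no longer passed, that of gained peaks was 1.25 without P1 replicate 3 and 3.09 without P1 replicate 2, and without P14 replicate 1 there were no called peaks to compare. Scaled to the reads between peaks, the odds ratio of gained peaks was 1.84. Across autosomes, the share of tested peaks that were lost ranged from 1.43% on chromosome 11 to 4.83% on chromosome 3, and the share gained from 0.03% on chromosome 16 to 0.21% on chromosome 7. Of 328 tested peaks on X, 2 were lost and 0 gained.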

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

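The fit within peaks, the likelihood ratio test, the enrichment covariate, the removal of both replicates 1 and the scaling to reads between peaks were chosen after seeing the data, and their alternatives with them. Over all regions, 0 calls became 83 with DESeq2, 1057 with the exact test, 2151 with the likelihood ratio test, 9 with the enrichment covariate, 7696 without both replicates 1, and 0 to 3341 with 1 library left out, the highest without P14 replicate 1. It stayed at 0 with limma-voom, DESeq2 size factors, no TMM, loess offsets, no filter, a mean of at least 20 reads, autosomes alone and an adjusted p under 0.01. Within peaks, 2479 calls became 3796 with the exact test, 4296 with limma-voom (100 gained, 4196 lost), 4128 with the likelihood ratio test, 774 with no TMM, 7326 when scaled to the reads between peaks, 323 without both replicates 1, 0 with the enrichment covariate and 0 at an adjusted p under 0.01. At a mean of at least 20 reads there were 483 (69 gained, 414 lost) among 59201 tested peaks. The called share there was 0.82%, against 2.56% of the 96785 peaks, so fewer tests alone do not account for the drop. Lost peaks held a median of 20.3 reads per library at P1 and 9.3 at P14, near or below that limit. The filter thus takes out many of them before the test, though how many was not counted. With 1 library left out there were 0 to 1470. DESeq2, DESeq2 size factors, loess offsets, no filter and autosomes alone gave 2407 to 3142. The cause of these differences was not tested.

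With the replicate number as a block, 0 regions and 0 peaks passed. The peaks called without the block then had a median log2 change of 1.42 for gained (1.47 without the block) and -2.12 for lost ones (-2.12). Not every library correlated best with its own number, and the block left the number of lists past the threshold at 23 and 1. Of the 23 lists called over all regions, 0 held with an estimated correlation and 23 with each library left out. The 1 list called within peaks did not hold with an estimated correlation, and with 1 library left out there were 0 to 1 lists. Fry asks whether a list changes at all, which is another question: over all regions it passed 0 lists in one direction and 17 in either, and within peaks 0 and 0.

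With 1 library left out, the odds ratio of gained peaks for gene spans ran from 1.25 to 17.1 and that of lost peaks from 0.651 to 0.993. When scaled to the reads between peaks the odds ratio was 1.84 for gained peaks and 0.553 for lost ones. That of lost peaks was 0.89 without both replicates 1, and neither value for lost peaks passed. Without both replicates 1 every gained peak lay in a gene span, which gives no finite odds ratio. The difference in reads on X was -0.0246 percentage points within the reads in peaks, and lost peaks on X were 0 with no TMM. Of the 70 named peaks past the threshold, 0 changed sign with other tests, scalings, the block or a library left out. The ages did not overlap in these peaks, so their choice left little room for a sign to turn. With the enrichment covariate, which is confounded with age, the sign turned at Dkk2 and Gli3 (0.03 and 0.03), and at 2 gained and 112 lost of all called peaks. The median log2 change of called peaks fell to 0.91 (median SE 0.47) from 1.47 (0.35) in gained and to -0.89 (0.82) from -2.12 (0.5) in lost ones, and 33 of 102 gained and 1426 of 2377 lost peaks fell below 0.5 of their change. Without P14 replicate 1 none of the 70 passed within peaks, where 0 peaks passed at all. Median log2 changes were then 1.48 for the 20 gained (1.73 with that library) and -1.93 for the 50 lost (-2.35 with that library). In the fit over all regions without that library, 17 of the 20 gained and 6 of the 50 lost passed. Within peaks without P1 replicate 1, 10 of the 20 gained and 20 of the 50 lost passed, with medians of 1.81 and -1.92. Offsets for CpG density, alone or with the block, another promoter definition and lists at promoters alone were not run, for want of a genome sequence and transcript starts. In simulated counts 4 of 100 changes of 2-fold were recovered within peaks.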

Other observations

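Some genes held several lost peaks. Tcf4, a basic helix-loop-helix transcription factor gene, had 13 of its 23 tested peaks lost, and Ryr2 had 9 of 17, the highest counts of any named gene. Macrod2 had 6 of 15 lost, Nfib 5 of 25, and Abcd3 and Wwtr1, which encodes the coactivator TAZ, 4 of 7 each. Among gained peaks, both tested peaks of Tradd, an adaptor of the TNF receptor, were gained, as were 2 of 8 at Shank3. These genes were picked after their values were seen, except Ryr2 and Shank3, and no test was made of their number. Without P14 replicate 1, 0 peaks passed within peaks, and without P1 replicate 1, 311 of all 2377 lost peaks did.

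All tests of explanations that follow were chosen after the results were seen, except the correlation across peaks and the splits over all regions. The share of reads in peaks was larger at P14. The log2 enrichment ratio ranged among the P14 libraries by 1.21 times the difference between the group means, but by 0.23 times without P14 replicate 1, so the first value rests on that library. Capture efficiency and a gain of methylation with age cannot be told apart here, with 2 other P14 libraries and no spiked-in or unenriched library used. The gain with age was not tested.

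Lost peaks within the peak fit may reflect capture as well as age. Taken without both replicates 1, so that neither chose them, such peaks lay lower in P14 replicate 1, the library with the highest share in peaks, than in the other P14 libraries by a median of -0.84 log2 (bootstrap interval -0.86 to -0.81) relative to other peaks of like abundance (-0.86 in the called peaks, on which this was first tested and which that library helped choose). They lay higher in P1 replicate 1, the one with uneven coverage, than in the other P1 libraries by 0.33 (0.3 to 0.35), and 0.87 in the called peaks. Each interval sets a single library against the others of its age, and does not measure the spread between libraries. Noise in single libraries is argued against as the whole source, since 2377 peaks chosen without a library were on the side of that library's age in all 6. The difference between ages was -1.55 log2, much of it from both replicates 1. Held-out medians were 1.31, 0.38 and 0.41 in P1 replicates 1 to 3, and -1.68, -0.46 and -0.43 in P14 replicates 1 to 3. A correlation across all tested peaks between contrasts that share no library, P14 replicate 1 against 2 and P14 replicate 3 against P1 replicate 2, was 0.08 (Spearman's rho, across peaks, which are not independent replicates), as capture efficiency would need; it, uneven coverage and age all stay open.

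Gained peaks may follow capture efficiency in the same way. Taken without both replicates 1, they lay higher in P14 replicate 1 than in the other P14 libraries by a median of 0.37 log2 (bootstrap interval 0.24 to 0.45) relative to other peaks of like abundance, and 0.53 in the called peaks. This interval too does not measure the spread between libraries. In 102 peaks chosen without a library, the held-out difference between ages was 0.5 log2. All 3 P14 libraries were higher, at 0.81 in replicate 1 but 0.25 and 0.16 in replicates 2 and 3. P1 replicates 1 and 2 were at 0.0, so noise in single libraries cannot be told apart from a difference with age here.

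With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The split by age called 0 regions over all regions, as did all 10 splits, the highest other being 0. Within peaks it called 2479, and 1 of 10 splits reached that number, the highest other being 0.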
